A study of Picea glauca with 72 samples.

How the data were processed

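Each of the 72 samples is 1 colour channel of a spotted oligonucleotide array of white spruce (Picea glauca), hybridised with amplified, dye-labelled RNA from the megagametophyte of a single seed. The seeds came from 2 unrelated mother trees, 77111 and 80112. Per the labels' protocols, they were cold-stratified and then kept warm in the dark for some hours before dissection. Tree and dye (Alexa647 or Alexa555) make 4 sets of 18 samples. In tree 80112 all 18 megagametophytes were measured with both dyes. In tree 77111, 16 of the 20 megagametophytes were measured with both dyes and the other 4 with a single dye, and those 4 entered only the fits that used all samples or the samples of a single dye. A replicate number names a megagametophyte within its tree, so samples with the same number and tree come from the same individual. A number that occurs in both trees names different individuals.

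The scanner files hold, for each of 34992 spots, the deposited trimmed mean intensity and the local background intensity, without normalization per the file headers, together with marks for spots of abnormal shape, dust or bright specks. All headers name the same wavelength, so the dye was taken from the labels. A quality column named in the labels' descriptions was not used here, and the marks took its place. The scanner software is not given in the sources used here. The deposited value table of the series is on a log2 scale. Its columns have the same sorted values within each set, with medians of 8.81, 8.49, 7.56 and 7.60 in the 4 sets, so it was quantile normalised separately in each set and its levels do not compare between trees. Its values lay close to normexp-corrected intensity with an offset of 50 (median absolute difference 0.06, 0.11, 0.03 and 0.05). The submitters' processing notes name limma, with no version. The deposited table was used as an alternative, with each column centred on its median.

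For the values used here, intensities were background corrected by normexp with an offset of 50 on all spots. They were then converted to log2, and the 32144 spruce probes were quantile normalised over all 72 samples. The 2848 control spots were left out at that step. Marked spots were set to missing. Marked spots made up 0.55% to 46.3% of a sample's spots, the highest being the Alexa555 sample of megagametophyte 79 of tree 80112 (46.3%) and the Alexa647 sample of its megagametophyte 67 (21.5%). A probe was tested if its intensity exceeded 1.5 times the local background in at least 0.5 of the samples of a tree and at least 12 megagametophytes had both dye values.

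Variation among megagametophytes was tested within each tree by the F-test of limma 3.58.1 (R 4.3.3), with the dye as covariate, so that differences among individuals were set against the disagreement between dye replicates. Repeatability is the mean square among minus the mean square within, over their sum. It estimates the share of the variance of a single sample that lies between individuals. Whether the dye replicates of an individual came from separate extractions is not given in the sources used here. RNA handling steps or hybridisation conditions that the replicates share count as differences between individuals. Two-class distributions were sought among probes past the F-test by the likelihood ratio of a mixture of 2 normal distributions with equal variance against 1 normal distribution, fitted to the mean of both dyes. The p came from 100000 simulated normal samples of the same size, so 1e-05 is the smallest it can be. Class sizes were set against 1:1 by an exact binomial test. The trees were compared by limma on the mean of both dyes per megagametophyte (16 against 18). The variances of the trees were compared by a 2-sided F-test of the mean squares. All p were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The mixture was fitted with Python 3.11.15, NumPy 2.4.6 and numba 0.67.0, the exact tests used SciPy 1.17.1, and mclust 6.1.1 gave an alternative criterion.

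The pairing of dye replicates was checked on their deviations from the set means. Every pair correlated above 0.1, with a mean of 0.54 in tree 77111 and 0.64 in tree 80112. The best match among the samples of the other dye was the own number for 13 of 16 and 16 of 18 megagametophytes. The labels do not say which channels shared an array. Spot diameters matched the channels of tree 77111 into 18 arrays, always of different individuals (correlation 0.46 to 0.63, next best at most 0.19). In tree 80112 only 9 of 18 matches were mutual. The array was therefore no term of the model, and the fit with it, marked spots kept, is given for tree 77111 as an alternative. On simulated values without differences among individuals, that fit called 14.6% of the probes when 0.9 of the variance was common to an array, and 0% when 0.5 was.

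The F-tests within trees and the comparison of tree means were checked on normal values simulated with the spread and missing values of the real probes. The variance test and the mixture were checked on standard normal values, with the missing values of the real probes for the mixture alone. Normal values cannot show false calls that come from outliers or skewed values. The exact and permutation tests were not checked. Among 50 probes each, an SD among individuals of 2 times the SD within was recovered for 64% in tree 77111 and 76% in tree 80112, and an SD of 4 times for 98% and 100%. Unchanged probes gave 5 and 3 calls. A log2 difference of 1 between trees was recovered for 86% and one of 0.5 for 36%. A variance ratio of 8 was recovered for 54% and one of 16 for 98%. Classes of 1:1 lying 6 within-class SDs apart were recovered for 46% in tree 77111 and 44% in tree 80112, and those 8 SDs apart for 92% in both. At the p of the last probe called in each tree, a less strict bound, simulated classes lying 6 SDs apart were detected for 79.1% with 3 and 79.4% with 8 individuals in the smaller class in tree 77111, and for 67.1% with 3 and 71.4% with 9 in tree 80112.

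The alternatives fixed before the data were examined were the deposited table, no background correction, median scaling, quantile normalization within each dye, other filters on dim probes, keeping the marked spots, a stricter threshold, the first principal component as covariate, an unmoderated F-test, leaving out each megagametophyte, each dye alone, a fit of all samples with the megagametophyte as a random block, and other criteria for classes and variances. The permutation of variance components was planned with 1000 draws and run with 100. Alternatives chosen after seeing the data were the background as covariate, the array as a random block, the overlap within 10 strata of mean intensity, and fits without single megagametophytes that stood apart. Probes carry only the array's own identifiers here, and the files used do not pair them with genes. Planned tests of gene lists and cell type markers were not run for that reason. Probes were named by a rule fixed before the data were examined, at most 2 in each direction: the largest SD among individuals within a tree, the largest differences between trees, and the smallest p for classes, with ties broken by the likelihood ratio.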

Results

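Transcript levels were measured in single megagametophytes of white spruce. The megagametophyte is the nutritive tissue of a conifer seed. It is haploid and derives from a single maternal meiosis, so sibling megagametophytes of a tree differ by the maternal alleles they received. The series carries 36 samples of 20 individuals of mother tree 77111 and 36 samples of 18 individuals of mother tree 80112, and its title speaks of heritable expression within single individuals of wild populations. Median net intensity of the spots ranged from 74.3 to 268.1 in the Alexa647 and from 53.4 to 211.6 in the Alexa555 samples of tree 77111. In tree 80112 it ranged from 27.0 to 102.9 and from 34.2 to 183.8. The share of spruce probes above 1.5 times background had medians of 45.3% and 70.7% for Alexa647 and Alexa555 in tree 77111, and of 41.0% and 68.9% in tree 80112. The number of individuals per tree limits the precision of all values below.

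The first comparison asked which transcripts differed among sibling megagametophytes beyond the disagreement of their dye replicates. In tree 77111, 7652 of 19903 tested probes varied among the 16 individuals (38.4%). In tree 80112, 14297 of 20236 varied among 18 (70.7%). Among varying probes, the median SD among individuals was 0.36 log2 units in tree 77111 (quartiles 0.25 and 0.56) and 0.43 in tree 80112 (quartiles 0.30 and 0.61). An SD above 1 log2 unit was found for 461 and 838 probes. In tree 77111, probe Spruce_04909 had an SD of 3.23 log2 units among individuals against 0.22 between dye replicates (n = 16, adjusted p = 4.23e-15). Its levels spanned 8.58 to 15.56 on the log2 scale. Spruce_22879 had 3.21 against 0.39 (n = 16, adjusted p = 3.92e-12), and the order of these probes turned under other settings, for instance 3.16 against 2.98 for Spruce_04909 in the deposited table. In tree 80112, Spruce_09727 had an SD of 3.27 against 0.33 (n = 17, adjusted p = 2.83e-14), and Spruce_04909 was again among the leading probes with 3.03 against 0.24 (n = 15, adjusted p = 2.87e-14).

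Over all tested probes, the median repeatability was 0.38 in tree 77111 and 0.62 in tree 80112. The SD between dye replicates was close in the trees (medians 0.25 and 0.26), while the SD among individuals was 0.18 and 0.34. When the dye replicates were paired at random 100 times, at most 5 probes in tree 77111 and 6 in tree 80112 passed the same F-test. With median scaling in place of quantile normalization the number in tree 77111 was 4420, and with the first principal component as covariate it was 11544. With the array as a random block and marked spots kept, a fit chosen after seeing the data, it was 18318 (92.0%), more than the share found in tree 80112, for which no such fit was made. The first principal component held 18.4% of the variance in tree 77111 and 28.7% in tree 80112, where it followed the median local background of the samples (Pearson's r = 0.947, permutation p = 1e-05, adjusted 2e-05; Spearman's rho = 0.924, permutation p = 1e-05, adjusted 2e-05; n = 18). These p are the smallest that 100000 permutations can give. Without the 2 individuals farthest from the median background, r was 0.941. In tree 77111 r was 0.420 (permutation p = 0.10, adjusted 0.10) and rho 0.385 (permutation p = 0.14, adjusted 0.14), and r was 0.638 without the 2 individuals farthest from the median. These 2 relations were all that were computed for the component. Their r and rho are given as sizes, since a component has no fixed sign.

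**Figure D1:**
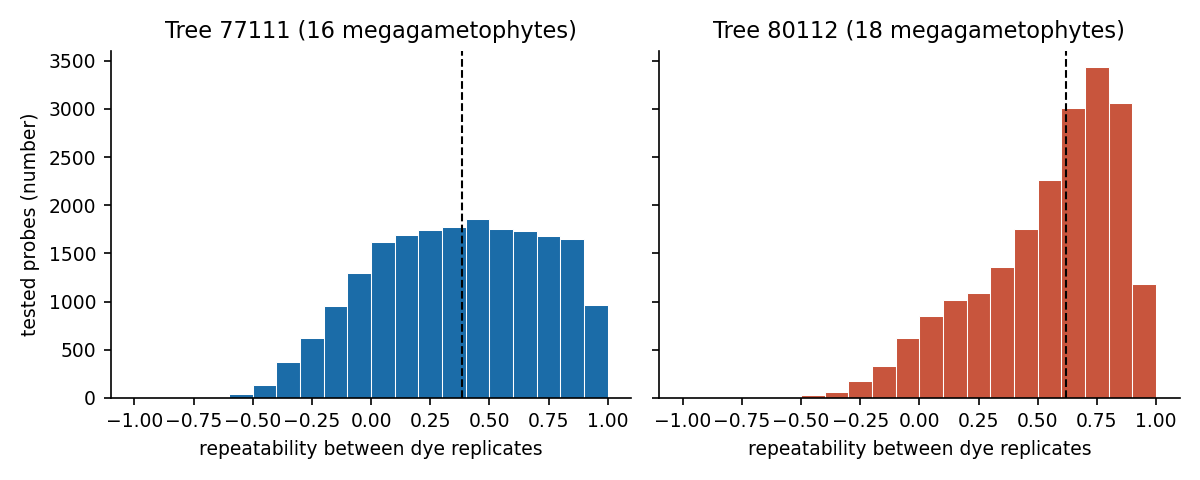
Number of tested probes (vertical axis) by repeatability between dye replicates (horizontal axis, no unit) in each tree, with the median as a dashed line. The median lies at 0.38 in tree 77111 and at 0.62 in tree 80112.

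The second comparison asked whether the same transcripts varied in both trees. Of 19864 probes tested in both, 6265 varied in both trees, where independent lists of that size would share 5400.3. The odds ratio was 2.61 (Fisher's exact test, 2-sided, 95% interval 2.43 to 2.80, p = 1.36e-176). Of the probes that varied in tree 77111, 82.1% also varied in tree 80112, against 63.7% of those that did not. Brighter probes varied more often in tree 80112, with 21.2% in the lowest and 81.5% in the highest of 10 strata of mean intensity. In tree 77111 these shares were 22.9% and 31.6%, so in the lowest stratum tree 80112 did not vary more often. Within these strata the odds ratio was 2.42 (95% interval 2.24 to 2.61). The odds ratio without strata, 2.61 as reported, was 4.57 without a filter on dim probes, 4.26 with the first principal component and 4.01 with the background as covariate. Probes are not independent of each other, so these intervals are too narrow.

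The third comparison asked whether the individuals of a tree fell into 2 expression classes, the shape that a heterozygous locus of the mother gives in haploid tissue. In tree 77111, 760 of the 7652 varying probes had 2 classes, and in tree 80112, 364 of 14297. In 475 and 210 of them the smaller class held at least 3 individuals. The class sizes did not differ from 1:1 by the exact binomial test for 435 probes in tree 77111 and 173 in tree 80112. With values from all individuals, any smaller class of at least 4 of 16 or 5 of 18 passes that test. Passing it is therefore weak evidence for 1:1. With the background as covariate, a fit chosen after seeing the data, 215 and 230 probes had 2 classes, 174 and 99 of them not different from 1:1, and with the first principal component 419 and 241 had, with 229 and 112. Without a covariate, the classes of the 435 and 173 lay a median of 1.42 log2 units apart in tree 77111 (quartiles 0.93 and 2.16) and 1.84 in tree 80112 (quartiles 1.21 and 2.43). In 27 of the 435 and 14 of the 173, no sample of the lower class was above 1.5 times background. In 133 and 28, all samples of the lower class were above it, so both levels were measured.

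The smallest possible p was reached by 143 probes in tree 77111 and 69 in tree 80112, among which Spruce_04909 and Spruce_32116 in tree 77111 and Spruce_17956 and Spruce_11359 in tree 80112 had the highest likelihood ratios. Spruce_04909 in tree 77111 had 6 individuals in the lower and 10 in the upper class, 6.44 log2 units apart with a within-class SD of 0.23 (n = 16, p = 1e-05, adjusted p = 5.35e-04). All samples of both classes were above background there. In tree 80112 the same probe had 4 individuals in the lower and 11 in the upper class, 6.59 units apart with an SD of 0.33 (n = 15, adjusted p = 0.00207), and 2 of the 8 samples in the lower class were above background. Spruce_32116 parted tree 77111 into 7 and 8 individuals, 2.33 units apart (SD 0.084, n = 15, adjusted p = 5.35e-04), and none of its 14 lower samples was above background, so that this distance is a lower bound. Spruce_11359 parted tree 80112 into 11 lower and 6 upper individuals, 3.22 units apart (SD 0.19, n = 17, adjusted p = 0.00207), with 6 of its 22 lower samples above background. In Spruce_17956, 1 individual of tree 80112 lay 2.28 units below the other 12 (SD 0.059, n = 13, adjusted p = 0.00207). The samples of these 12 lay between 15.31 and 15.65, near the highest value among the named probes (15.70). Whether a ceiling of the scale narrows this SD was not tested. The leading varying probes had 2 classes as well, with 8 and 8 individuals for Spruce_22879 in tree 77111 and 6 and 11 for Spruce_09727 in tree 80112. Of their lower samples, 6 of 16 and 9 of 12 were above background. With the background as covariate the classes of Spruce_04909 in tree 77111 no longer passed (separation 5.21, adjusted p = 0.44), and with the first principal component those of Spruce_17956 did not (1.91, adjusted p = 0.061).

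**Figure D2:**
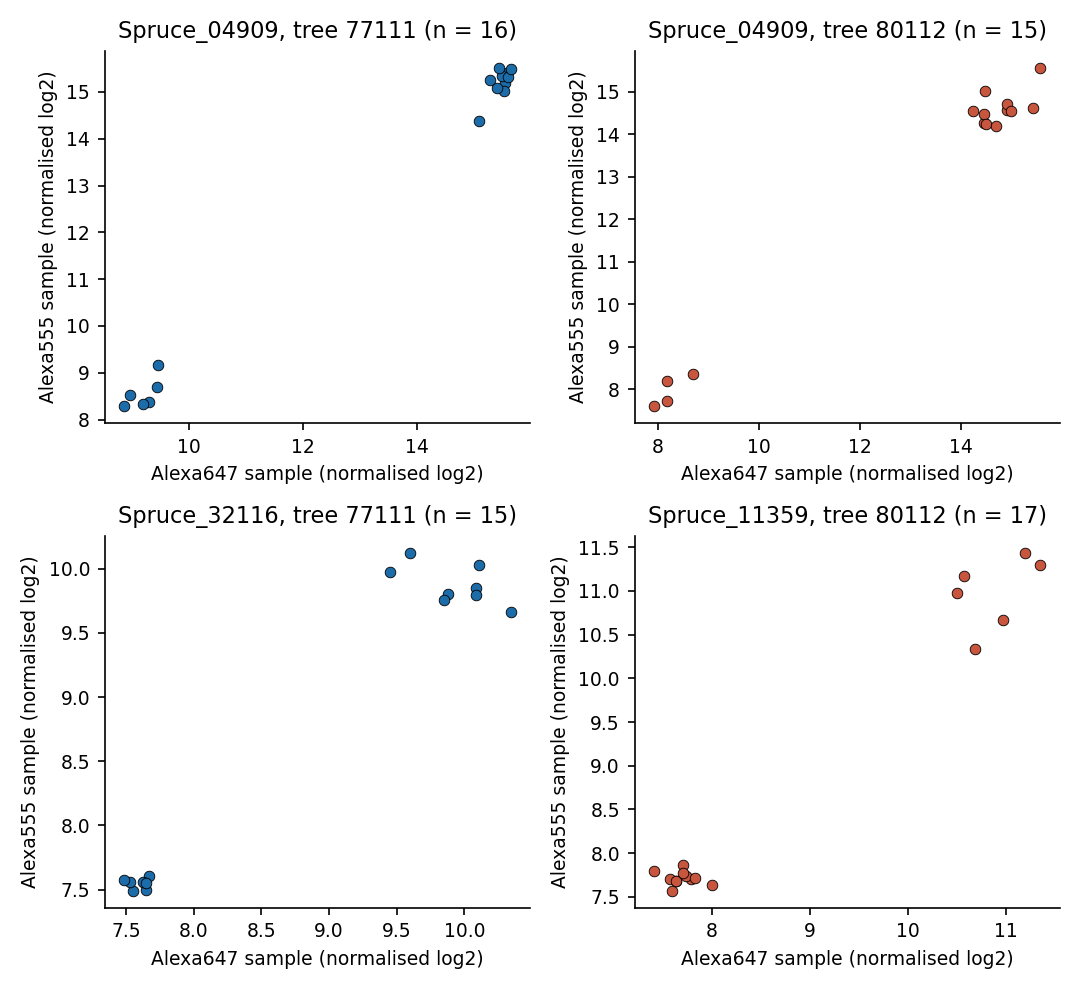
Normalised log2 intensity of the Alexa555 sample (vertical axis) against that of the Alexa647 sample (horizontal axis) for probes with 2 classes, 1 point per megagametophyte. Both dyes place each individual in the same class, for instance 6 low and 10 high individuals for Spruce_04909 in tree 77111.

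The size of the smaller class could be compared with 1:1 for the probes with values from all individuals. In tree 77111 this held for 340 probes with 2 classes, of which 192 had at least 5 individuals in the smaller class and 98 had 1. In tree 80112 it held for 74 probes, with 34 and 22. Classes of a single individual were concentrated in tree 77111: megagametophyte 68 stood alone in 186 of 227 such probes, at the higher level in 184. Without that individual, tree 77111 had 498 probes with 2 classes.

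**Figure D3:**
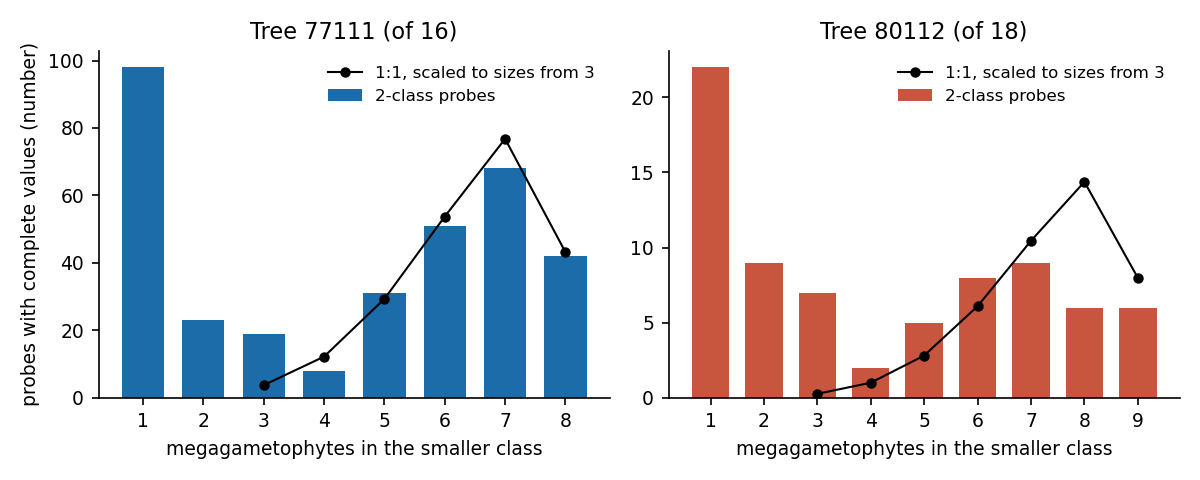
Number of 2-class probes with complete values (vertical axis) by the number of megagametophytes in the smaller class (horizontal axis) in each tree. Black points give the 1:1 expectation, scaled to the observed total of classes of at least 3. In tree 77111, 68 probes have a smaller class of 7 and 98 have a smaller class of 1.

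The fourth comparison set the trees against each other. Of 19864 probes, 9814 differed in mean level (49.4%), 5183 higher and 4631 lower in tree 77111. The median size of these differences was 0.54 log2 units (1.46-fold), and 1478 exceeded 2-fold, 775 higher and 703 lower in tree 77111. Spruce_07605 had the largest difference, with 7.97 ± 0.29 (SD, n = 15) in tree 77111 and 14.55 ± 0.49 (SD, n = 16) in tree 80112, a log2 difference of -6.58 (SE 0.14, adjusted p = 4.02e-26). It was above background in 13 of 32 samples of tree 77111 and in 36 of 36 of tree 80112, and no individuals of the trees overlapped. Spruce_03089 was lower in tree 77111, with a log2 difference of -4.42 (SE 0.66, adjusted p = 2.43e-06) and means of 9.04 ± 2.55 (SD, n = 14) against 13.46 ± 1.13 (SD, n = 17), and its tree 77111 values were split into 12 low and 2 high individuals. Megagametophyte 54 was high as well in Alexa647 (15.17), but was left out because its Alexa555 spot was marked. With marked spots kept the difference was -3.96. Spruce_02175 was higher in tree 77111, 13.79 ± 0.59 (SD, n = 15) against 9.16 ± 1.24 (SD, n = 15), by 4.63 (SE 0.34, adjusted p = 4.72e-12), without overlap. Spruce_04927 was higher by 4.38 (SE 0.67, adjusted p = 2.73e-06), 14.50 ± 0.33 (SD, n = 15) against 10.12 ± 2.65 (SD, n = 17). It was above background in 25 of 36 samples of tree 80112, where megagametophytes 67 and 79 lay at the level of tree 77111. When the samples of each dye were tested alone, 6637 probes differed in both dyes in the same direction and 23 in opposite directions. The seed lot goes with the tree, and so may the hybridisation series. Tree and series cannot be told apart.

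**Figure D4:**
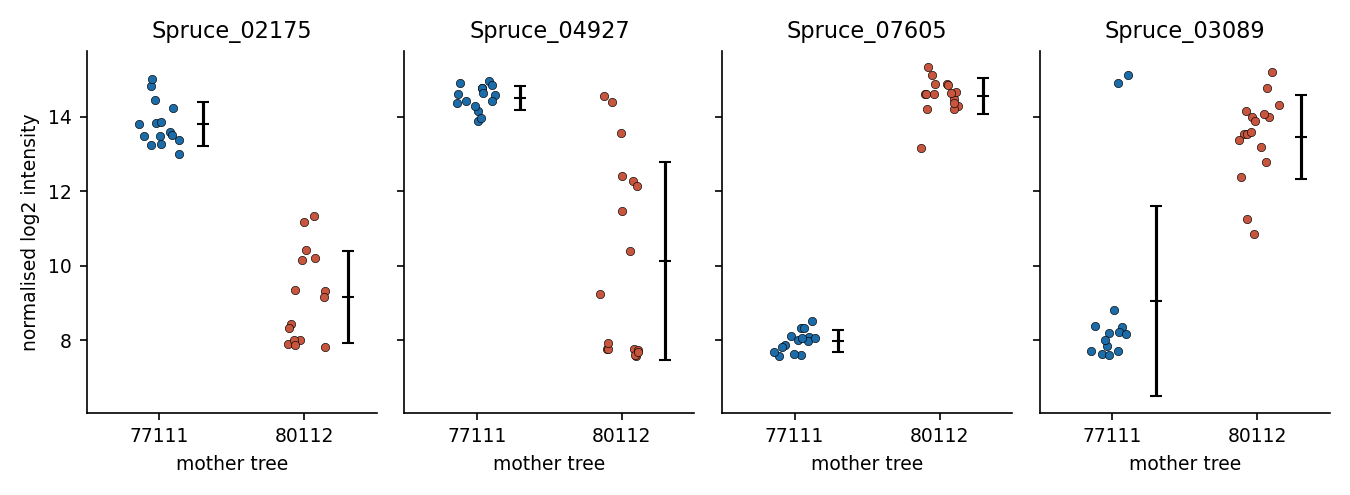
Normalised log2 intensity (vertical axis, mean of both dyes) of the 4 named probes in the megagametophytes of each tree (horizontal axis), with mean and SD as bars. Spruce_07605 separates the trees fully, while Spruce_03089 has 2 individuals of tree 77111 at the level of tree 80112 among those with both dye values.

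The fifth comparison tested whether variation among siblings differed between the trees. The variance among individuals differed for 5749 of 19864 probes, higher in tree 80112 for 5002 and in tree 77111 for 747. The median ratio of the mean squares, tree 80112 over tree 77111, was 2.13, and 78.5% of all probes had the higher value in tree 80112. The F-test for variances relies on normal values. When the variance components were compared by 100 permutations of the trees, 510 probes passed the same threshold, 395 higher in tree 80112 and 115 in tree 77111. With the first principal component as covariate the number was 3746 and with the background as covariate 3393, with median ratios of 1.67 and 1.60.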

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

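The fits with the first component, of each dye alone and with an individual left out were fixed before the data were examined, while the tests of explanations made from them and the other tests in this part were chosen after the results were seen. The first result is the difference in variation between the trees, 5749 probes by a test of the difference itself. Only 1 of 100 splits of the 34 megagametophytes, the real one, gave as many, and the highest other gave 520. That argues against chance, although 100 splits cannot exclude it. The larger number of individuals in tree 80112 is argued against: random sets of 16 gave at least 64.8% of varying probes, above the 42.8% that tree 77111 reached at most when an individual was left out. Array background that differs among individuals is argued against as the whole source, since with it as covariate 55.6% of the probes of tree 80112 varied, against 40.5% in tree 77111, but it may account for part of the 70.7% found without it, and with the first component as covariate the shares were close (59.9% and 58.0%) while the median variance ratio was 1.67. Arrays shared by different individuals may lower the calls of tree 77111, since 92.0% of its probes varied with the array as a random block, and this stays open because the arrays of tree 80112 were not resolved and the fit called up to 14.6% of simulated unchanged probes. Whether the first component of tree 80112, which follows the background, reflects hybridisation or the state of the seeds stays open, as does a difference in heterozygosity or seed lot of the mothers, which was not tested. Hybridisation conditions shared by the dye replicates of an individual stay open too. The median backgrounds of the replicates were correlated in tree 80112 (Pearson's r = 0.590), against r = -0.187 in tree 77111.

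The second is the mean difference between the trees, 9814 probes. Only 1 of 100 splits, the real one, gave as many, and the highest other gave 66, so chance is argued against here too. A dye offset common to both trees cancels, since each megagametophyte entered as the mean of both dyes. For the probes called in each dye alone, the selection itself leaves out a tree difference carried by 1 dye. Of them, 99.7% had the same direction in both dyes. A tree difference carried by 1 dye stays open for the 3203 of the 9814 that were not called in each. Of these, 97.2% had the same direction in both dyes, but calling on the mean of both dyes favours a shared direction. A hybridisation series that goes with the tree may be a source for any of them: control spots for green fluorescent protein, a sequence foreign to spruce, were 19.2-fold brighter in tree 77111 (permutation test, 2-sided, p = 1e-05, the smallest that 100000 resamples can give), although the control spots named alien did not follow in Alexa555. Tree and series cannot be told apart, since the labels give no series that spans both trees.

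The control spots entered no comparison of spruce probes. The median net intensity of the green fluorescent protein spots averaged 9184 ± 2832 (SD, n = 18) in the Alexa647 and 12016 ± 2868 (SD, n = 18) in the Alexa555 samples of tree 77111. In tree 80112 it averaged 231 ± 157 (SD, n = 18) and 2039.95 ± 1205 (SD, n = 18). The alien spots averaged 5.26 ± 4.98 and 18.4 ± 17.1 (SD, n = 18) in the Alexa647 and Alexa555 samples of tree 77111, and 2.004 ± 1.71 and 33.6 ± 29.6 (SD, n = 18) in those of tree 80112. The differences of the alien spots were not tested. Empty positions averaged between -0.40 and 0.07 in the same 4 sets.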

How the results depend on the processing

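Alternatives moved counts of calls. The tree differences of the 4 named probes kept their direction in all 15 alternatives for each. SDs and class separations cannot be negative, so they could not change direction. Of the values of named probes and of the overlap, 177 of 179 stayed past the threshold. The probes were chosen as the most extreme in the same data, and several alternatives leave their values unchanged. That count is therefore a weak check. The number of probes differing between the trees ranged from 7160 to 12234 and that varying in tree 80112 from 11247 to 15035, both within 1.5 times of the reported numbers. The fit with the megagametophyte as a replicate block gave 10491 probes between the trees (estimated correlation 0.517). It was run for this comparison alone, where the 4 named probes kept their direction and passed as well. Leaving out single individuals gave 6492 (without 68) to 8306 probes in tree 77111, 13170 to 14451 in tree 80112 and 9149 to 9871 between the trees. For the larger changes below the cause was not tested, except where fewer probes, individuals or a stricter criterion explain it by construction. Probes varying in tree 77111 numbered 4420 with median scaling, 11544 with the first principal component as covariate and 18318 with the array as a random block and marked spots kept (estimated correlation 0.918), against 7917 with marked spots kept alone. Probes varying in both trees numbered 3294 with median scaling and 3807 at an adjusted p under 0.01. Probes of unequal variance numbered 10635 without a filter, 3047 at 0.01, 3746 with the first component, 3393 with the background as covariate and 510 with permuted variance components. Probes with 2 classes in trees 77111 and 80112 numbered 1229 and 825 without a filter, 449 and 180 at 2 times background, 377 and 157 at 0.01, and 475 and 210 with at least 3 in the smaller class. With the first component they numbered 419 and 241, and with the background 215 and 230. In tree 77111 a BIC difference above 10 gave 457, and leaving out megagametophyte 68 gave 498. The fits with the background, with the array block and without megagametophyte 68 for the classes were chosen after seeing the data. A level near background bounds a difference from below.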

Other observations

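Of the tests in this part, those on shared classes between the trees and on permuted background were written before their results were seen, the others after. Probes with 2 classes were shared between the trees. Of the 6265 probes varying in both, 374 in tree 77111 and 114 in tree 80112 had at least 3 individuals in the smaller class, and 19 had so in both, where independent lists share 6.81 (odds ratio 3.27, Fisher's exact test, 2-sided, p = 3.73e-05). Spruce_04909, with classes over 6 log2 units apart in either tree, was one of them. A hypothesis is that some transcripts have alleles of distinct level in unrelated trees, and 19 probes in common is consistent with that. Probes of high or cross-hybridising signal could give the same excess and were not tested.

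Several probes parted the siblings in the same way. In tree 77111, 219 probes with complete values and at least 3 individuals in the smaller class gave 157 distinct partitions, and 96 pairs of probes had identical ones. Shuffling the individuals within each probe 1000 times gave a mean of 0.927 and at most 5 such pairs. In tree 80112, 43 probes gave 38 partitions and 6 identical pairs, against at most 1 in the shuffles. The smallest p that the shuffles can give is 0.001, and both trees reached it. Pairs such as the 96 and the 6 may come from linked loci, from a locus acting on several transcripts, or from probes of the same transcript. A technical split shared by some probes could give them too. These sources were not told apart here.

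The third pattern weighed is the existence of the classes themselves. An identical technical split across the probes with complete values and at least 3 individuals in the smaller class is argued against. The most common partition held at most 6.98% of them in either tree. A shared split with some individuals misplaced stays open. Linking partitions at most 2 individuals apart put 93 of 219 probes of tree 77111 in 1 group. In tree 80112 the largest such group held 6 of 43. Partitions were linked in chains, so members of a group may lie more than 2 apart. No shuffled reference was made, and the trees differ in numbers of probes and individuals, so these group sizes decide nothing. For classes of 1 a technical split stays open. Megagametophyte 68 held 81.9% of those in tree 77111. It had the highest background of the 16 (8.06 against at most 7.89 on the log2 scale, mean of both dyes), which may be the source. However, megagametophyte 71, at 7.89, held 0 of these classes, and megagametophyte 55, at 7.19, held the next most (11). By spot diameters the 2 samples of megagametophyte 68 lay on different arrays, so no single array held both. Megagametophyte 80 held 23.6% in tree 80112 with a background of rank 12 of 18 (6.42, highest 8.71). That rank goes against high background as the source of its own classes only. Megagametophytes 59, 37 and 71 held the next most (22, 16 and 15), with high backgrounds of 7.73, 8.27 and 8.44. Megagametophyte 44, with the highest of 8.71, held 0. High background thus stays open for the other classes of 1 in tree 80112. Array background as a source of classes stays open in both trees. In tree 80112, with background as covariate on the same probes, 215 had 2 classes. That lay above the 128 to 206 left by 20 permuted backgrounds, which was set beforehand as going against it. The count cannot decide, since a covariate that follows expression can sharpen some classes while it removes others. In tree 77111, 227 lay inside the range set beforehand as going against it (213 to 526). That was far below the median of 408, with 2 of the 20 as low. Segregation of 1:1 as the only source is argued against in tree 80112, where 79.1% of classes of at least 3 had 5 or more individuals (95% interval 61.4% to 94.3% when groups of probes linked by partitions at most 2 individuals apart were resampled), against 97.0% from 1:1 and 71.4% if sizes were uniform, and it stays open in tree 77111, where the share was 87.7%, above the 66.7% of uniform sizes, and the upper limit lay between 92.68% and 96.7% when partitions at most 0 to 2 apart were grouped, about at or above the 92.7% from 1:1. Whether a class reflects transcript level or a sequence difference under the probe was not tested.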
